A study of Rattus norvegicus with 2 samples.

How the data were processed

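RNA sequencing compared 2 libraries of rat bone marrow mesenchymal stem cells (bmMSCs), the plastic-adherent stromal cells of bone marrow, from Sprague-Dawley rats. One library came from untransfected cells, which the submitters used as the negative control, and the other from cells collected 10 days after transfection with Pdx1 and Ngn3 (gene symbol Neurog3), transcription factors of pancreatic and endocrine development. Per the labels' protocols, RNA was extracted with a trizol method, messenger RNA was selected with oligo(dT) beads and fragmented, complementary DNA was primed with random hexamers, and the amplified fragments were sequenced on an Illumina GA instrument. The protocols name no strand-marking step. Genome build rn4 is given in the submitters' processing notes. The aligner, the counting tool and the treatment of reads shared between genes are not given in the sources used here. Each row's description in the deposited table quotes a representative rat cDNA and its UniGene cluster, so counts refer to cDNA clusters, and no genome coordinates are given.

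The deposited table holds read counts, the authors' whole numbers of reads per gene without scaling. It also holds RPKM (reads scaled by gene length in kilobases and by library total), which the authors computed from those counts, with 0.001 written where a library had 0 reads. Gene length is a further deposited column. The authors' deposited log2 ratio is the log2 of the transfected over the untransfected RPKM, and a p-value and a false discovery rate were deposited for each gene, from a test that is not named in the sources used here. The table is a selection: in the authors' deposited table the smallest absolute log2 ratio was 1.00 and the largest false discovery rate 0.000996. Every gene in it had therefore already passed a change of at least 2-fold in the authors' test, and genes outside it were not analysed here. The authors' p-values come from the reads of 1 library per condition. They compare those libraries, not the conditions, and were not used for any statement below.

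The table has 2325 rows. Of these, 1665 carry the identifier and symbol of a rat gene, and 1630 of those identifiers matched a RefSeq gene of the GRCr8 assembly, which was used for names only. The current RefSeq symbol differed from the deposited symbol in 214 rows, and deposited symbols are used throughout. Another 595 rows have no symbol. In 65 rows the identifier is the sequence number of a rat cDNA, and the symbol attached to it belongs to a gene of another organism. These 660 rows (28.4%) stayed in the gene counts but name no gene. The length column differed from the length in the description in 11 rows. Dividing counts by length and RPKM gave 1 total per library, 7800831 reads for the untransfected and 7415094 for the transfected library, in all but 1 row (Actg1 in the untransfected library). These implied totals were taken as library depths, since the column sums cover listed genes alone.

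For each gene, the ratio of transfected to untransfected reads was computed after division by the library totals, with an exact 95% interval from the binomial share (Clopper-Pearson) of the 2 counts. Levels were recomputed as RPKM with exact Poisson intervals. A library at 0 reads was set to 3 reads, the 1-sided 95% limit that a count of 0 allows, so the fold of such a gene is a lower bound against that floor. This floor is less strict than the 2-sided exact intervals used for other genes, and it takes the reads of the other library as counted. The lower limit of the exact interval is therefore given beside such folds. These intervals and floors cover counting error only, and PCR reads without molecular identifiers are not independent molecules. With 1 library per condition there is no estimate of the spread between cultures or animals, no test across replicates could be made, and no p-value is given. A gene was counted as higher or lower when its ratio was at least 2 and its interval excluded 1. The planned design assumed a table that might hold all genes. Because it holds only selected ones, no gene could fall between the limits.

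Before the data were examined, 34 gene lists were fixed for the tissue and treatment, along with the alternatives and the rule for naming genes. The rule named Pdx1 and Neurog3, the 10 genes higher and the 10 lower with the largest fold by the interval bound nearest to 1 (predicted loci left out), and from each list the 4 changed members with the highest mean RPKM, or the 2 highest where none had changed. It also named every listed islet hormone and endocrine transcription factor. Some genes that the rule named are not reported here. Genes named outside the rule are marked as chosen after their values were seen. For lists with at least 3 members in the table, the median log2 ratio was placed among 10000 random lists of equal size. These were drawn from all 2325 rows, with or without a rat gene symbol, and matched on mean RPKM in 10 bins. List members all carry such a symbol, and 1016 of the 1665 rows that do were higher, against 1476 of all rows. The random lists therefore leaned further to the higher side than rows that could be members, and the effect on percentiles was not tested. Because all listed ratios lie beyond 2-fold, a median jumps between the sides when members are split, so the share of higher members was also placed among random lists, a measure chosen after seeing the data. Percentiles describe these 2 libraries. Across 25 lists, 1.25 would lie beyond the 2.5 or 97.5 percentile by chance.

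The alternatives were TMM scaling (edgeR) and median-of-ratios scaling, both on the listed genes, a minimum mean RPKM of 1, ratios of log2(RPKM + 1), a minimum fold of 4, no interval, an interval with an assumed biological coefficient of variation of 0.4, unmatched random lists and means in place of medians. Scaling by the reads outside the table, and counting only rows with a rat gene symbol, were added after seeing the data. The counting rule was tested on simulated data for the 2325 genes of this comparison: with 200 genes changed, it recovered 97.5% of those changed 4-fold, 97% of those changed 3-fold and 50% of those changed 2-fold, where the threshold itself lies, with none in the wrong direction. It also called 9, 7 and 15 unchanged genes in these simulations. The simulated reads held Poisson counting noise alone, without spread between cultures, and most simulated genes were unchanged, unlike those in the table. These figures are therefore not error rates for the real comparison. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, R 4.3.3 and edgeR 4.0.16.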

Results

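The data comprised 1 library of untransfected rat bmMSCs and 1 library of bmMSCs taken 10 days after co-transfection with Pdx1 and Ngn3. The implied depth was 7800831 reads for the untransfected and 7415094 reads for the transfected library. The genes in the deposited table held 21.7% of the untransfected reads and 20.2% of the transfected reads. A listed gene had at least 13 reads over both libraries, with a median of 232, and 101 genes had fewer than 30. The comparison addresses how the transcriptome of bmMSCs differed after these pancreatic factors were introduced. The control was untransfected, so the procedure of transfection differs between the libraries along with the introduced genes, and the time in culture of the control is not given in the sources used here. No difference below has a replicate check, and each stated interval covers counting error only.

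Of the 2325 listed genes, 1476 were higher and 849 were lower in the transfected library, with median changes of 3.41-fold and 3.10-fold. The largest increases were in Igfbp5, an insulin-like growth factor binding protein, which had 4 reads in untransfected and 4630 in transfected cells (1218-fold, interval 475 to 4471). Cxcl13, a B-cell attracting chemokine, was 432-fold higher (198 to 1178), and Ace, angiotensin-converting enzyme, was 412-fold higher (176 to 1272). Ass1, the argininosuccinate synthase of the urea cycle, went from 0 to 638 reads and was at least 224-fold higher against the floor (exact lower limit 181). The other genes in this group were Pdx1, Mamdc2 (at least 164-fold against the floor, exact lower limit 133) and Mybpc1 (at least 163-fold against the floor, exact lower limit 132). The serpin Serpina3n (162-fold), the neuronal pentraxin Nptx1 (249-fold) and the microfibril protein Mfap4 (167-fold) completed it. The largest decreases were in Tinagl1, a basement membrane protein (54.0-fold lower, interval 35.8 to 85.5), Pgm5 (44.7-fold) and Prima1 (39.3-fold). Cspg4, the pericyte proteoglycan NG2, was 23.3-fold lower at 3.93 against 91.3 RPKM. Wisp2, Mylk, Cnn1, Sema7a and Timp3 also belonged to this group, from 14.7-fold lower for Cnn1 to 39.9-fold lower for Timp3, the last with 3 transfected reads and an interval of 13.4 to 196. The bound of the interval nearest to no change passed 10-fold for 112 higher and 22 lower genes. Of 25 gene lists with at least 3 listed members, 4 had a median at or above the upper percentile limit of random lists and 8 at or below the lower limit, or 3 and 5 with means in place of medians. On the upper side only the inflammatory list passed with both measures. The beta cell, matrix and complement lists passed with medians alone, and the neuronal and the growth factor binding lists with means alone. By the share of higher members, the measure added because medians jump between the sides, only the inflammatory list passed the upper limit (percentile 98.2). Only the contractile and cholesterol lists passed the lower limit by that share, both at percentile 0. TMM and median-of-ratios scaling, computed on genes selected for change, moved all log2 ratios by -0.78 and -1.20 and so could only remove higher calls from this table, which left the higher genes at 46.4% and 37.6% of calls, against 63.5% here. With an assumed biological coefficient of variation of 0.4 the counts were 783 higher and 401 lower genes.

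**Figure D1:**
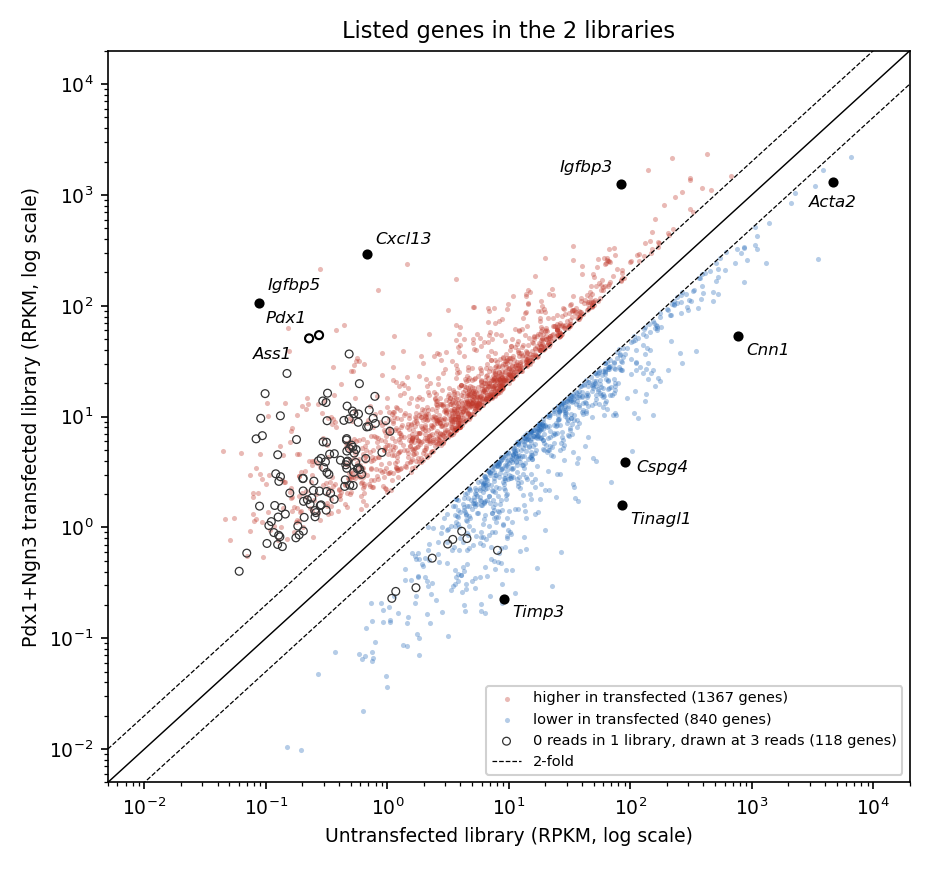
Level of each listed gene in the untransfected (x axis) and the transfected library (y axis), both in RPKM on log scales; each point is 1 gene, red if higher and blue if lower in transfected cells, black if named, open if 1 library had 0 reads and was drawn at 3 reads, with solid and dashed lines at equal levels and at 2-fold. No point lies between the dashed lines, because the table holds only genes past 2-fold, and 109 genes had 0 reads in the untransfected library against 9 in the transfected library.

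Pdx1 had 0 reads in the untransfected library, which allows up to 0.274 RPKM at the 3-read floor, and 565 reads in the transfected library (54.3 RPKM, interval 49.9 to 59.0). It was at least 198-fold higher against that floor (exact lower limit 161). The authors' deposited table gives Pdx1 a log2 ratio of 15.73, which rests on the 0.001 RPKM written for 0 reads. Reads of the introduced and the endogenous Pdx1 cannot be separated here. Neurog3 was not analysed here. None of the 8 islet hormones, the 28 endocrine transcription factors or the 22 exocrine and duct markers in the fixed lists was among the listed genes, and they were not analysed here. From 23 genes of beta cell function, 3 were listed and all 3 were higher. These were Cpe, carboxypeptidase E, which trims prohormones (2.97-fold, at 389 and 1154 RPKM), Pcsk2, prohormone convertase 2 (15.3-fold, interval 5.65 to 57.9, from 4 to 58 reads), and Gjd2, a gap junction protein of neurons and beta cells. Gjd2 had 0 and 39 reads (at least 13.7-fold against the floor, exact lower limit 10.6). The median of these 3 lay at percentile 98.2 of matched random lists and their share of higher members at percentile 88.2. Under ratios of log2(RPKM + 1) the percentile of the median was 92.8, and the mean of the members lay at percentile 96.1. Of 24 endoderm and epithelial genes, Ttr, transthyretin, was the one listed, at 3.61-fold higher.

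Neuronal genes, 5 listed from 24 fixed, were higher in transfected cells in 5 of 5 cases. Dcx, the microtubule protein doublecortin of young neurons, was 41.5-fold higher (interval 21.6 to 91.5, from 9 to 355 reads). Tubb3, the neuronal beta-III tubulin, was 4.69-fold higher at 66.3 RPKM, Nes, nestin, 5.57-fold, and Nefh, a neurofilament subunit, 3.45-fold. Apart from Tubb3, the named neuronal genes stayed below 10 RPKM in both libraries. Of 24 granule and exocytosis genes, 6 were listed, 4 higher and 2 lower: Scg2, secretogranin II, was 58.9-fold higher (interval 22.7 to 218) and Unc13a, a vesicle priming factor, 3.21-fold lower. The other lower member, Vgf, a granule protein named after its values were seen, was 28.8-fold lower (121 and 4 reads). Rab3a, a vesicle GTPase, was 2.30-fold higher, a direction that turned under median-of-ratios scaling, which left 3 of the 6 above 0. Of 24 Notch pathway genes, 4 were higher and 1 lower. Dll1, a Notch ligand, had 3 and 94 reads (33.0-fold, interval 10.9 to 163), Heyl, a Notch target, 2 and 42 reads (22.1-fold, interval 5.75 to 188), Hes6 was 3.06-fold higher and Notch4 4.28-fold lower. The medians of the neuronal, granule and Notch lists lay at percentiles 87.3, 63.9 and 92.6, inside the range of random lists, and the Notch median moved to percentile 98.5 against unmatched lists and the neuronal mean to 99.4.

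Contractile and actin-associated genes were lower: of 22 fixed genes 17 were listed, 15 lower and 2 higher. Tagln, transgelin, was 2.98-fold lower (6522 and 2186 RPKM), and Acta2, smooth muscle actin, was 3.58-fold lower (4648 and 1298 RPKM). Myl9, a myosin light chain, was 2.49-fold lower and the actin crosslinker Flna 2.59-fold lower. Cnn1, calponin, was 14.7-fold lower (778 and 52.9 RPKM) and Mylk, myosin light chain kinase, 21.8-fold lower (15.7 to 31.1). The exceptions, named after their values were seen, were Synpo2, an actin-binding protein (18.6-fold higher), and Rgs5, a pericyte marker. Rgs5 had 0 and 39 reads (at least 13.7-fold higher against the floor, exact lower limit 10.6). The list's median lay at percentile 0.12 and its share of higher members at percentile 0, below every one of the 10000 random lists. Acta2 belongs to a family of near-identical actins, and its count is uncertain because the treatment of shared reads is not given.

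Surface and stromal markers of mesenchymal stem cells went both ways, with 5 higher and 6 lower among 11 listed of 23. Thy1, the stromal marker CD90, was 3.41-fold lower (1101 and 322 RPKM), Itgb1, integrin beta 1 or CD29, 2.04-fold lower and Itga5 3.08-fold lower. Kitlg, stem cell factor, was 11.2-fold higher. The median of this list lay at percentile 23.5. Osteoblast genes were split, with 3 higher, among them Bmp4 (15.3-fold) and Tnfrsf11b, osteoprotegerin (10.3-fold), and 2 lower, Alpl, alkaline phosphatase (11.7-fold), and Dlx3 (14.6-fold), at percentile 65.4. Of 5 listed adipocyte genes 3 were higher, with Lpl, lipoprotein lipase, at 7.33-fold and Cebpd at 2.89-fold, and Scd1, a fatty acid desaturase, was 3.46-fold lower. The adipocyte median (1.18) and mean (-0.033) of the log2 ratios differed in sign, the median lay at percentile 44.7, and Adfp (2.26-fold higher) and the median turned below 0 under median-of-ratios scaling. Of the chondrocyte genes Cilp was 6.06-fold higher and Acan, aggrecan, 2.17-fold lower.

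**Figure D2:**
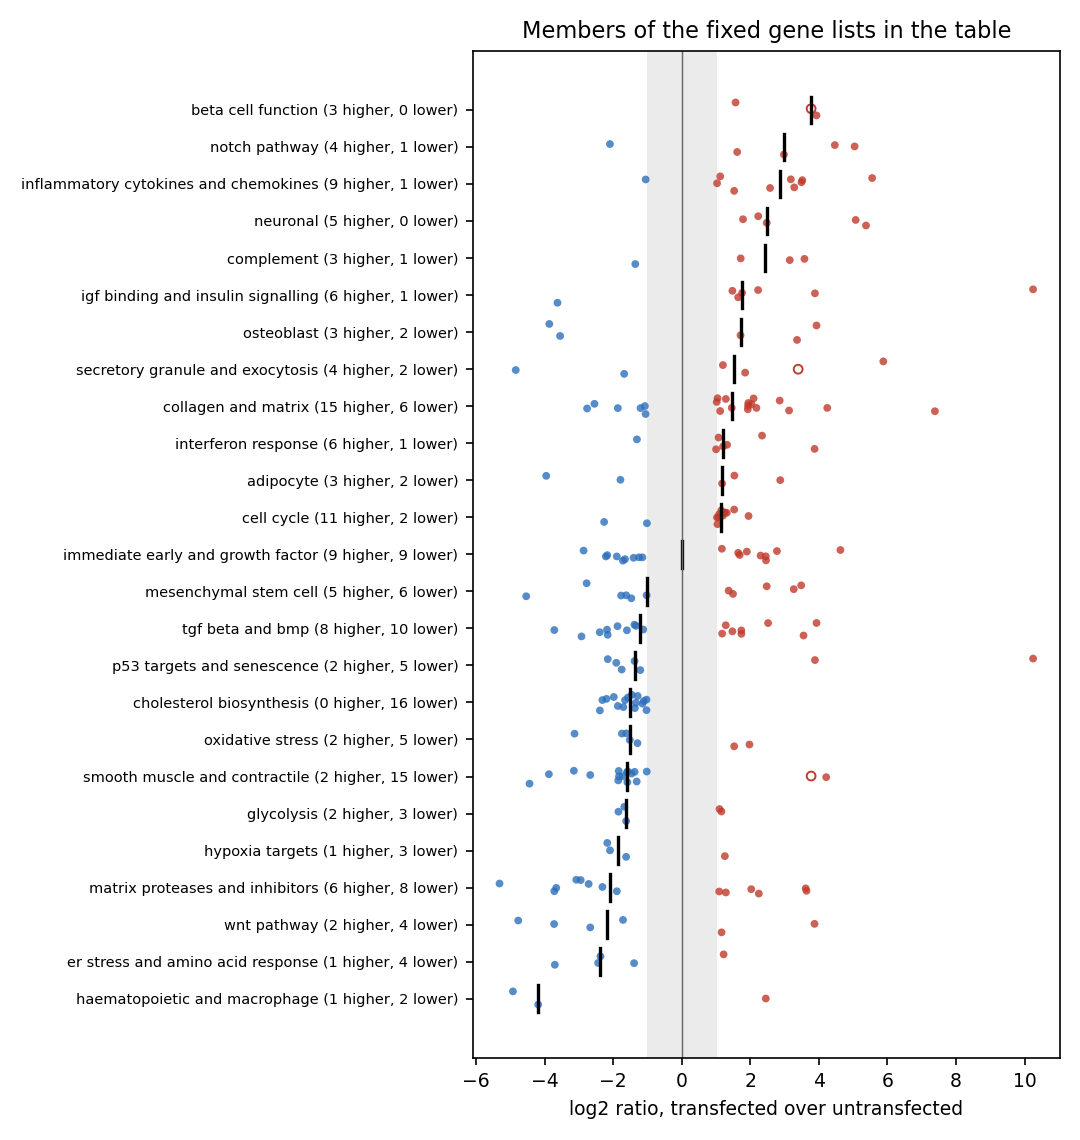
Log2 ratio of transfected over untransfected reads (x axis) for each listed member of the 25 fixed gene lists with at least 3 members in the table (y axis); points are genes, open where the untransfected library had 0 reads, black bars are list medians, and the grey band marks less than 2-fold. All 16 listed cholesterol genes and 15 of 17 contractile genes lie on the lower side, and 9 of 10 inflammatory genes on the higher side, 7 of 10 under median-of-ratios scaling.

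Extracellular matrix genes were more often higher than lower, 15 against 6 of the 21 listed from 42, or 12 against 9 under median-of-ratios scaling. Postn, periostin, was 4.52-fold higher (313 and 1415 RPKM), Dcn, decorin, 4.27-fold higher and Col8a1 2.44-fold higher. Thbs1, thrombospondin 1, the listed gene with the most untransfected reads (111717), was 2.30-fold lower. The median of the list lay at percentile 98.9, but at 80.5 against unmatched lists, the mean at percentile 97.3 and the share of higher members at percentile 94.4. Proteases and their inhibitors were split, 6 higher and 8 lower, with Serpinh1 (2.13-fold higher) turning under median-of-ratios scaling. Mmp2, gelatinase A, was 2.44-fold higher (459 and 1118 RPKM) and Timp1, an inhibitor of such proteases, 4.08-fold higher, whereas Timp3 was among the lower members. The median of the list was below that of every random list (percentile 0), and its share of higher members lay at percentile 15.3. Among 18 listed genes of the TGF-beta and BMP pathways, 8 were higher and 10 lower, or 7 and 11 under median-of-ratios scaling. Tgfb3 was 5.26-fold lower, the TGF-beta binding protein Ltbp1 3.67-fold lower and Ctgf, connective tissue growth factor, 3.03-fold lower, while Chrd, the BMP antagonist chordin, named after its values were seen, was 11.7-fold higher, with the median at percentile 1.10 and the mean at 7.5. Of 6 listed Wnt pathway genes 4 were lower, including the antagonists Wif1 (13.2-fold) and Nkd2 (6.37-fold) and Wisp2 (27.3-fold), and the Wnt-binding protein Sfrp2 was 14.6-fold higher. The other higher member, Fzd8, named after its values were seen, turned under median-of-ratios scaling. The Wnt median lay at percentile 0.12 and the share of higher members at 8.38. Growth factor binding and insulin signalling genes were higher in 6 of 7 listed cases from 18 fixed genes. Among them were Igfbp5 at 1218-fold, Igfbp3 at 14.8-fold (84.4 and 1247 RPKM), Akt2 at 3.38-fold and Igf1 at 3.13-fold. The exception, Igfbp2, named after its values were seen, was 12.4-fold lower (39 and 3 reads, interval of the ratio 0.016 to 0.255). For this list the median lay at percentile 93.5. The mean, which includes the log2 ratio of 10.25 of Igfbp5, lay at 99.

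Inflammatory genes, a list of cytokines, chemokines and related enzymes and proteins, had 10 listed of 39. They were higher in 9 of 10 listed cases, or 7 of 10 under median-of-ratios scaling, where Ptgs2 and Cx3cl1 turned. Cxcl6, a neutrophil-attracting chemokine, was 9.72-fold higher (220 and 2138 RPKM), Il6, interleukin 6, 11.4-fold higher (interval 9.57 to 13.8) and Sod2, the mitochondrial superoxide dismutase, 2.88-fold higher. Ptgs2, cyclooxygenase 2, was 2.04-fold higher. Cx3cl1 and the lower member Nos2, nitric oxide synthase 2 (2.08-fold lower), were named after their values were seen. The median of the list lay at percentile 99.99 and its share of higher members at 98.2. Complement genes were higher in 3 of 4 listed cases from 19 fixed genes. Serping1, the C1 inhibitor, was at 140 RPKM in untransfected and 1669 RPKM in transfected cells. C1s was 8.88-fold higher and Clu, clusterin, 3.29-fold higher, while Cd55, a complement inhibitor of the cell surface, was 2.56-fold lower. The complement median lay at percentile 98.6 of matched and 93.9 of unmatched lists, the mean at 92.7 and the share of higher members at 78.3. Interferon response genes had 7 listed of 62, 6 of them higher, or 4 under median-of-ratios scaling, where Parp9 (2.10-fold higher) turned. The guanylate binding protein Gbp5 was 14.7-fold higher, Gbp2 was at 6.85 and 17.1 RPKM, and the transcription factor Irf9 was 2.30-fold higher, while Trim21, named after its values were seen, was 2.48-fold lower, with the list's median at percentile 40.5. Among markers of blood cells, 3 of 39 were listed. Cd74, the invariant chain of antigen-presenting cells, was 18.3-fold lower (96 and 5 reads) and RT1-Db1, a class II histocompatibility gene, had 32 and 1 reads (30.4-fold lower, interval 5.08 to 1239). Cd68, a macrophage marker, was 5.47-fold higher, from 5 to 26 reads, and over these 3 genes the median lay at percentile 0.135 and the mean at 3.48. Of the endothelial genes, Egfl7 was listed, at 3.37-fold lower.

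Genes of cholesterol biosynthesis were lower in 16 of 16 listed cases from 25 fixed genes. Among them were Sc4mol, the sterol C4-methyl oxidase (2.53-fold, 136 and 53.7 RPKM), Cyp51, lanosterol demethylase (3.26-fold), Sc5dl (3.96-fold) and Fdps, farnesyl diphosphate synthase (2.58-fold). The median lay at percentile 0.20 and the share of higher members at percentile 0. Genes of the endoplasmic reticulum and amino acid stress response were lower in 4 of 5 listed cases from 39 fixed genes. Asns, asparagine synthetase, was 2.63-fold lower, Chac1 5.18-fold lower and Trib3 13.0-fold lower (96 and 7 reads), while Aldh1l2 was 2.33-fold higher; the median lay at percentile 0.595, or 3.12 with ratios of log2(RPKM + 1), and the share at 3.07. Hypoxia targets were lower in 3 of 4 listed cases from 20 fixed genes. Vegfa, vascular endothelial growth factor A, was 4.52-fold lower and Car9 4.27-fold lower, with Bnip3l 2.39-fold higher. The median lay at percentile 1.78 of matched and 2.76 of unmatched lists and the mean at 5.72. Glycolysis genes, 5 listed of 20, were split, 2 higher and 3 lower. The higher ones, Hk1 (2.23-fold) and Pfkm (2.14-fold), turned under median-of-ratios scaling. Slc2a1, the glucose transporter, was 3.08-fold lower and the lactate transporter Slc16a3 3.60-fold lower. This list's median lay at percentile 3.12, but its mean at 10.8 and its share of higher members at 17.9. Among antioxidant genes Gpx3 was 3.07-fold and Gpx1 2.87-fold lower and Sod3 3.93-fold higher, at percentile 3.03 for 2 higher and 5 lower.

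Of 60 cell cycle genes 13 were listed, 11 higher and 2 lower, or 5 and 8 under median-of-ratios scaling. The mitotic genes Kif20a (2.10-fold) and Ube2c (2.06-fold) were higher but turned under that scaling, while Ccnd1, cyclin D1, was 4.81-fold lower and Ccnd2 2.03-fold lower. The median was 2.22-fold higher at percentile 33.0 and turned below 0 under median-of-ratios scaling (-0.050). Targets of p53 and senescence genes were lower in 5 of 7 listed cases from 26 fixed genes, including Gadd45g (2.32-fold) and Pmaip1, the BH3 protein Noxa (3.76-fold). The higher members were Igfbp3 and Igfbp5, and the median and mean log2 ratios differed in sign (-1.38 and 0.82). Their percentiles were 4.56 for the median and 73.0 for the mean. Immediate early and growth factor genes were split, 9 higher and 9 lower, or 8 and 10 under median-of-ratios scaling, with Angptl4 5.46-fold and Spry1 4.92-fold higher and Hbegf 3.15-fold lower. Their median log2 ratio was 0.010, at percentile 11.8, and lay below 0 under the other 3 scalings. Of 76 ribosomal protein genes Rpl41 was listed, with 6 and 72 reads, and none of the 46 respiratory chain genes was.

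**Figure D3:**
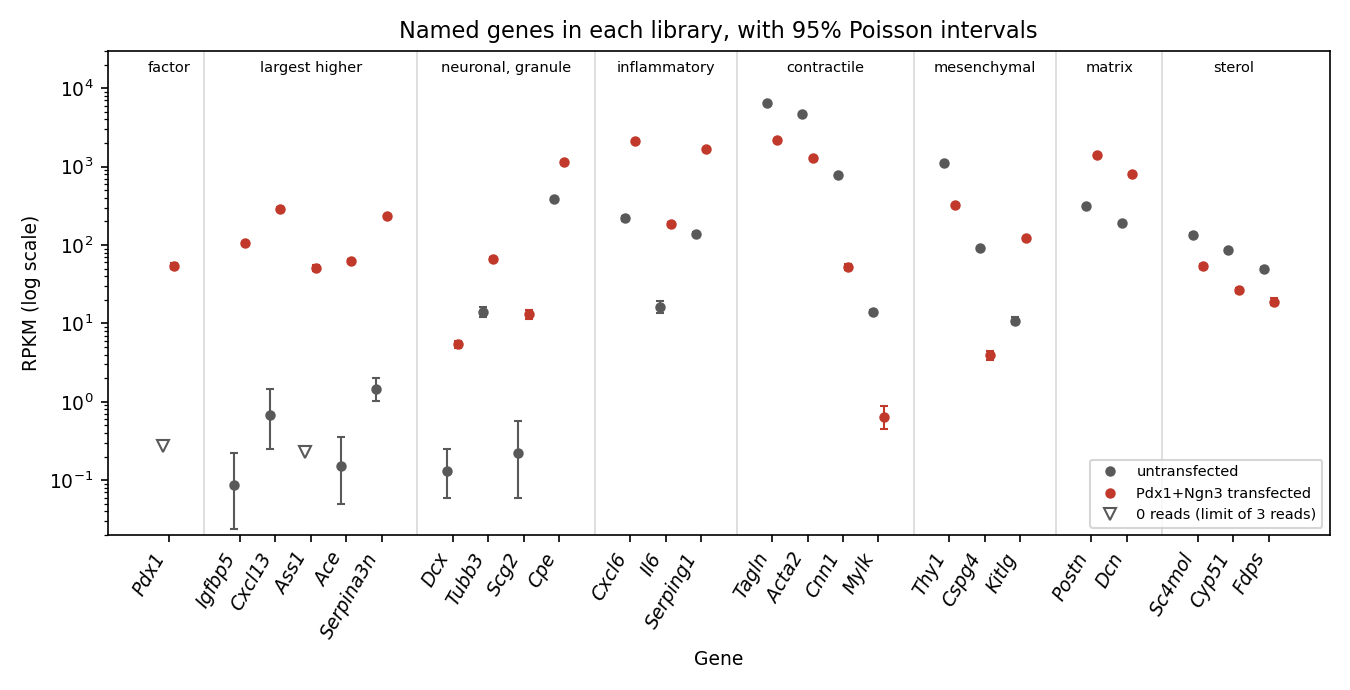
RPKM on a log scale (y axis) of named genes (x axis) in the untransfected (grey) and the transfected library (red); points are single libraries, bars are 95% Poisson intervals for counting error, and open triangles mark the limit of 3 reads where the untransfected library had 0. The intervals of the libraries do not overlap for any gene drawn, which the selection of listed genes for change largely fixed in advance. Folds run from 2.53-fold for Sc4mol to 1218-fold for Igfbp5.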

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

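Scaling by the reads outside the table and the restriction to rows with a rat gene symbol were chosen after seeing the data. No paired analysis was possible because each condition had 1 library, and for the same reason no replicate could be left out. The counts of 1476 higher and 849 lower genes became 734 higher genes under TMM scaling and 512 under median-of-ratios scaling, by the shifts of -0.78 and -1.20 that these factors add to every log2 ratio, with the lower count fixed at 849 because genes outside the table were not analysed here. A minimum fold of 4 left 617 higher and 286 lower genes, by construction, and an assumed biological coefficient of variation of 0.4 left 783 and 401, by its wider intervals. The minimum RPKM, log2(RPKM + 1) and rat-symbol settings gave counts within 1.5 times of these. The no-interval and outside-reads (shift -0.028) settings could hardly move them, since the table holds only genes selected for change. Means in place of medians left 5 lists rather than 8 at or below the lower percentile limit. At or above the upper limit they left 3 rather than 4, of which only the inflammatory list also passed with medians. Medians of split lists jump between the sides here, because all listed ratios lie beyond 2-fold. In the TGF-beta and BMP list, with 8 higher and 10 lower, the median lay at percentile 1.10 and the mean at 7.5. Whether this accounts for every change between the measures was not tested. Of 114 named genes other than Pdx1, 9 changed sign under median-of-ratios scaling, all higher by less than its shift: Adfp (log2 ratio -0.026), Hk1 (-0.045), Kif20a (-0.13), Parp9 (-0.13), Pfkm (-0.10), Ptgs2 (-0.17), Rab3a (-0.0021), Serpinh1 (-0.11) and Ube2c (-0.16). A count of 0 allows 3 reads, so ratios of genes with few reads are loosely bounded.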

Other observations

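The tests on Gene Ontology terms, library totals, reads outside the table, rat-symbol genes at 0 reads, class II genes and mock transfection were chosen only after the result was seen. Gene Ontology process terms carried in the deposited table were used to describe further groups. Among 95 terms with at least 15 listed genes, 5 had a median at or above the upper percentile limit of matched random lists and 10 at or below the lower limit, where 2.38 would lie on each side by chance. The terms share genes and are not independent. Their random lists were drawn only from rows with a rat gene symbol, unlike those for the fixed lists. The terms named here are a selection, and their percentiles are those of medians. Extracellular structure organization had 18 of 25 genes higher (percentile 99.5), G-protein coupled receptor signalling 21 of 29 (98.9) and defense response 32 of 47 (97.9). For comparison, 1016 of all 1665 rows with a rat gene symbol were higher, and shares of higher genes were not placed among random lists for these terms. Muscle system process had 11 of 17 genes lower (percentile 0.020) and cell-substrate adhesion 11 of 17 (1.68). Protein modification process reached percentile 0.025 with 30 genes higher and 37 lower, so a split term can have an extreme median. RT1-DMb, a class II histocompatibility gene outside the fixed lists, was named after its values were seen: it had 37 untransfected and 4 transfected reads and was 8.79-fold lower, the direction of Cd74 and RT1-Db1.

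The untransfected library had 109 listed genes at 0 reads and the transfected library 9, which is 7.38% of the higher and 1.06% of the lower genes. The totals argue against an untransfected library with fewer reads, as it was 1.05 times as deep as the transfected one. Total reads do not count distinct molecules, so they decide depth alone. Abundant genes taking up the untransfected reads stay open. Scaling by the reads outside the table moved log2 ratios by 0.028, but listed genes held only 21.7% and 20.2% of the reads, and genes outside the table were not analysed here. The 10 highest listed genes of each library held 6.86% of the untransfected and 4.44% of the transfected reads. Among the genes at 0 untransfected reads, 43.1% (lower exact Clopper-Pearson limit 33.7%) were cDNA rows without a rat gene, against 27.7% of the others, but so were 6 of the 9 genes at 0 transfected reads, so this share does not show that such rows produce the asymmetry. As its whole cause they are argued against, because 62 genes with a rat symbol were at 0 reads in the untransfected library and 3 in the transfected library. A start of transcription in genes silent before transfection stays open as an untested hypothesis, as does a difference between the cultures.

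The 15 lower contractile genes are a pattern for follow-up. An effect that follows gene length is argued against, because the list's median lay at percentile 0.19 of random lists of listed genes matched on length. RNA breakdown that does not follow gene length stays open, because matching on length cannot detect it. Scaling stays open, because each alternative scaling lowered all log2 ratios, so the highest median of -1.60 was fixed as the value under library totals. An effect of transfection or of days in culture, rather than of Pdx1 and Ngn3, may underlie it and cannot be told apart, since 0 mock-transfected libraries are in the comparison. A lower contractile program under the introduced factors is the biological hypothesis, untested by this design.

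The 9 higher genes of the inflammatory list are the last pattern weighed. More antigen-presenting leukocytes in the transfected culture are argued against, because Cd74, RT1-Db1 and RT1-DMb were all lower there, with a highest upper limit of the ratio of 0.317. That test was chosen with these values already seen, and it measures transcripts of whole cultures rather than numbers of cells. Macrophages with few class II transcripts are left open by that test, as Cd68 was higher. The lowest median log2 ratio of that list under the 4 scalings was 1.68, so no scaling tried removed the rise of the median. For single genes scaling stays open, because Ptgs2 and Cx3cl1 turned under median-of-ratios scaling, which left 7 of the 10 listed genes above 0. The TMM and median-of-ratios factors rest on genes selected for change and do not bound the error of scaling. A response to transfection or culture could produce the same values and cannot be told apart, again with 0 mock-transfected libraries.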
